A study of Homo sapiens with 9 samples.

How the data were processed

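RNA of MDA-MB-231 cells was sequenced 48 hours after transfection with a control siRNA, MILIP siRNA1 or MILIP siRNA2, with 3 libraries per group and 9 in all, grouped by the treatment labels. The deposited table holds a count per gene and library, which the authors made before deposit. Per the submitters' processing notes the tools were Trimmomatic 0.30, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq, without saying which step each did. The deposited FPKM values were made from these counts by the authors, and dividing each count by exonic gene size and library total gives 100% of them within 0.005. The notes name hg19, but the gene coordinates in the table are those of GRCh38, with 99.98% of 58394 identifiers in GENCODE v29 overlapping the same gene on the same chromosome. The strandedness of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Gene names came from a reference table for 60401 of 60612 identifiers, and the name in the file was used for the 211 others.

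The design was fixed before the data were examined. It set limma on log2(FPKM+1) as the test unless the table also held counts, in which case edgeR on the counts was to be used and the FPKM fit to become an alternative. The table holds counts. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR's quasi-likelihood test in 1 fit of the 3 groups, two-sided, with Benjamini-Hochberg adjustment and calls at an adjusted p below 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). Levels are TMM-scaled counts per 1e+06 counts of a library (CPM). The 3 comparisons were each siRNA against control and siRNA2 against siRNA1. The 34 gene lists cover translation, cell cycle, stress, inflammation, metabolism, mitochondria, cell death, signalling and markers of fibroblasts, leukocytes, endothelium and epithelium, and were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The targeted gene also had an exact permutation test. Principal components were computed on log2 CPM. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the search of 7-base words in 3 prime UTRs of GENCODE v29 and for the figures. Gene Ontology terms of 10 to 500 genes were tested with a hypergeometric test and Benjamini-Hochberg adjustment, from annotation deposited with the table.

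Named genes follow a rule set in advance. They are MILIP and MELTF-AS1, the 12 genes higher and the 12 lower with both siRNAs with the largest smaller fold change, the 6 largest in each direction for each comparison, a fixed set (MYC, YBX1 and others), and up to 4 of the most changed members of each list. For the sets of 12 and of 6, all libraries lie on 1 side of the group they are set against, and clone or accession names were left out. Neither was required of the fixed set and the list members. MAFG and NOTUM were added after their values were seen, and so were the genes named with Gene Ontology terms. Of 192 named genes 35 overlap a gene on the opposite strand and 8 one on the same strand.

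The depth of 15281220 to 19759371 counts per library gives 0.152 to 0.196 CPM for 3 counts, and the common biological coefficient of variation was 0.0641. The calls were tested on simulated data with the means and spread of these libraries: edgeR recovered 50% of changed genes at the smallest fold simulated, 78% at 1.5-fold, 80% at 2-fold and 98% at 4-fold, with 12 false calls in a test of 15345 genes. The changed genes were drawn only from the more abundant tested genes, so these shares do not cover genes of low counts. Far fewer genes were changed there than were called in the real data. Pairs of libraries of a group differed by a chi-square of 2.18 to 8.78 per gene, and no 2 libraries were identical. Alternatives were DESeq2, median-of-ratios scaling, no filter, a minimum mean FPKM of 1 or 5, limma on FPKM with 5 choices of pseudocount, scaling and moderation, a replicate block, the 2 groups alone, each library left out, a fold minimum, and, chosen after seeing the data, leaving out genes whose 3 prime UTR holds a word linked to either siRNA. Some genes that the rule names are not reported here. Genes below the filter (45267) were not tested, and raw reads were not used here.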

Results

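The study asked which transcripts change when MILIP, a long noncoding RNA, is depleted from MDA-MB-231 cells, a human triple-negative breast cancer line. RNA was sequenced 48 hours after transfection of a control siRNA, MILIP siRNA1 or MILIP siRNA2, with 3 libraries per group and 9 in all. Total gene counts ranged from 15281220 to 19759371 per library. Among 60612 listed genes, 15345 had enough counts to be tested, and these held 99.87% of all counts. A gene with 0 counts in a library may still be present at up to 3 counts, which is 0.152 to 0.196 CPM depending on the library, a limit that covers counting error only. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

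The 3 groups separated from each other. The first principal component of log2 CPM held 47.8% of the variance and set siRNA1 (-45.7 to -43.7) apart from siRNA2 (46.1 to 48.5), with the control libraries between them (-5.5 to -0.8). The second held 31.3% and set the control libraries (42.3 to 43.5) apart from both siRNAs (-24.4 to -17.8). Mitochondrial ribosomal RNA took 0.622% ± 0.0282 of counts in control libraries, 1.1% ± 0.121 with siRNA1 and 0.893% ± 0.0265 with siRNA2, while mitochondrial protein-coding transcripts took 4.37% ± 0.102, 4.93% ± 0.254 and 4% ± 0.0369 (SD, n = 3 each).

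MILIP fell with both siRNAs. Its level was 8.41 ± 0.254 CPM in control libraries, 1.24 ± 0.641 CPM with siRNA1 and 0.616 ± 0.316 CPM with siRNA2 (SD, n = 3 each), which left 14.7% and 7.32% of the control level. The counts behind these values were 133, 126 and 148 in the control libraries, 19, 11 and 37 with siRNA1, and 10, 19 and 6 with siRNA2. The log2 fold change was -2.74 (SE 0.256, adjusted p = 2.51e-09) with siRNA1 and -3.73 (SE 0.287, adjusted p = 5.34e-11) with siRNA2, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. MILIP was lower with siRNA2 than with siRNA1 (log2 fold change -0.99, adjusted p = 0.0264), although the libraries of these groups overlapped. An exact two-sided permutation test of each siRNA against control gave p = 0.1, the smallest that 3 against 3 libraries allow.

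MILIP is listed as MAFG-DT (ENSG00000265688) on chromosome 17, plus strand, positions 81927829 to 81930753 in GRCh38 coordinates. Its longer transcript has 2 exons, from 81927829 to 81928445 and from 81929476 to 81930753, and no coding part. MAFG, which encodes a small Maf transcription factor, lies head to head with it on the minus strand (81918270 to 81927735), and the 5 prime ends of these gene spans are 94 bases apart. MAFG rose with both siRNAs, from 158 ± 7.38 CPM to 214 ± 2.14 CPM with siRNA1 (log2 fold change 0.43, adjusted p = 7.17e-07) and 185 ± 6.79 CPM with siRNA2 (0.23, adjusted p = 0.00155). MAFG was chosen for its position after its values were seen, and it overlaps SIRT7 on the same strand. The treatment text names siRNAs against PLANE, which is the gene MELTF-AS1, where the title and the treatment labels name MILIP. MELTF-AS1 (ENSG00000228109) was at 2.39 ± 0.811 CPM in control libraries, 2.88 ± 0.361 CPM with siRNA1 and 2.06 ± 0.349 CPM with siRNA2 (SD, n = 3 each), and passed the test with neither (log2 fold change 0.26, adjusted p = 0.392, and -0.23, adjusted p = 0.469). MELTF-AS1 overlaps MELTF on the opposite strand, and its counts were low (26 to 64 per library).

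**Figure D1:**
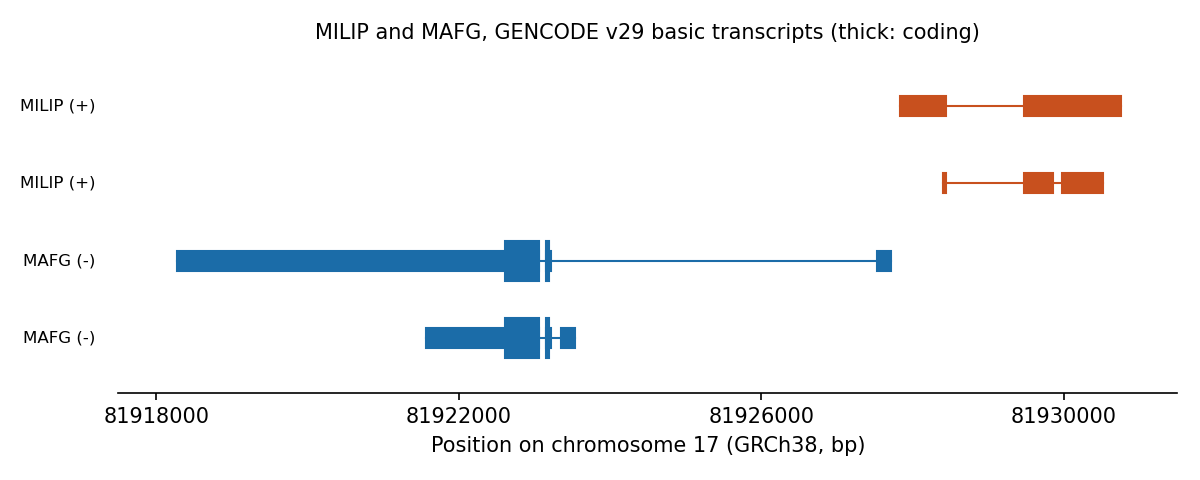
Exons of MILIP (plus strand) and MAFG (minus strand) on chromosome 17 in GRCh38 base positions, from the GENCODE v29 basic annotation, with introns as lines and coding parts drawn thicker. The genes run away from each other on opposite strands.

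**Figure D2:**
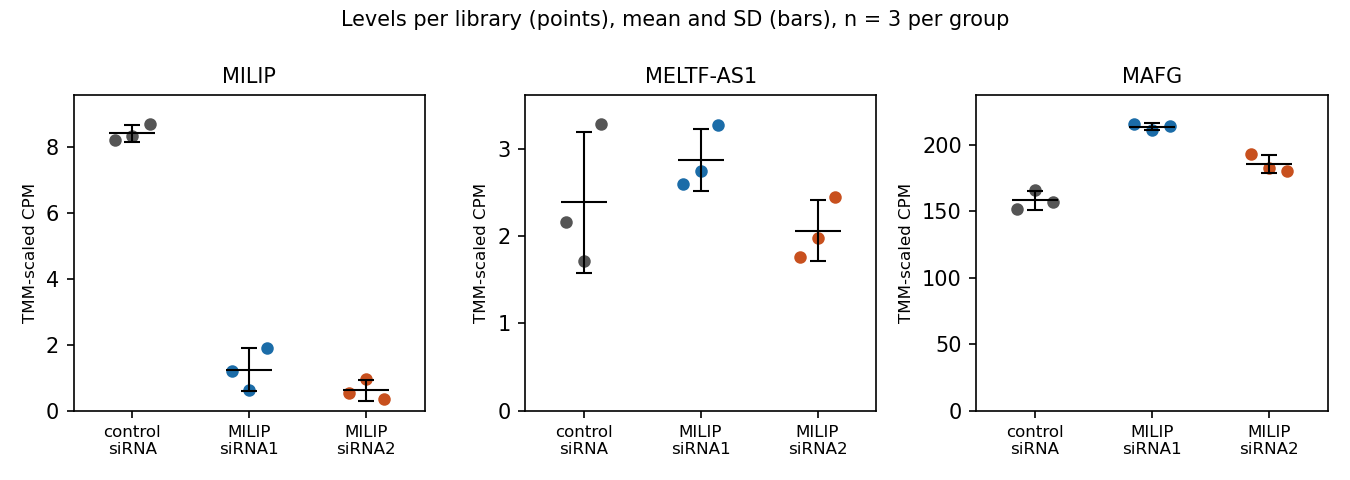
Levels of MILIP, MELTF-AS1 and MAFG in CPM for each of the 9 libraries (points), with the group mean and SD as bars (n = 3 per group). MILIP was at 8.21 to 8.7 CPM in the control libraries and at 0.349 to 1.9 CPM with the siRNAs, and MAFG was higher in all siRNA libraries than in any control library.

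With each siRNA the 7-base word most linked to lower transcripts by its t value is a word that MILIP also holds. Of the 15952 words tested, 9.53% occur in MILIP. Among 7-base words in the annotated 3 prime UTRs of 12533 tested genes, AATTCCA had the lowest t with siRNA1 (-20.07, a shift of -0.31 on the log2 scale over 2117 UTRs), and GACCCTA the lowest t with siRNA2 (-16.31, a shift of -0.42 over 668 UTRs). The siRNA1 word lies in the last exon of MILIP at positions 81930360 to 81930366 of chromosome 17, and the siRNA2 word at 81930484 to 81930490 of the same exon. The 2981 genes with the siRNA1 word, or with ATTCCAA, the form 1 base along, had a median log2 fold change of -0.20 with siRNA1, against 0.051 in genes without either. The 1358 genes with the siRNA2 word or its form ACCCTAA, which MILIP does not hold, had a median of -0.24 with siRNA2, against 0.024. Each word was picked by its t on these same fold changes, so a lower median among its genes follows in part from the choice. The sequences of the siRNAs were not used here. For the genes named below the presence of either word or its form is stated as a fact of their 3 prime UTR.

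In the lists of G1/S, ribosome biogenesis and spliceosome genes 40 of 48, 25 of 40 and 19 of 39 members were lower with both siRNAs, and 12 of 23 TGF-beta targets were higher with both. These 4 lists lost their call with siRNA1 (adjusted p = 0.414, 0.529, 0.529 and 0.414 with an estimated correlation), and TGF-beta targets also with siRNA2 (adjusted p = 0.0501 with an estimated correlation). AXL, a receptor tyrosine kinase of mesenchymal cells, fell from 1004 ± 34.7 CPM to 103 ± 3.92 CPM with siRNA1 and 273 ± 11.3 CPM with siRNA2. ATOH8, a helix-loop-helix transcription factor, rose from 1.34 ± 0.178 CPM to 15.1 ± 1.47 and 16.1 ± 0.481 CPM. SNAI1, a transcription factor of epithelial-mesenchymal transition, rose from 1.67 ± 0.287 CPM to 6.4 ± 0.484 and 5.75 ± 0.849 CPM (SD, n = 3 per group throughout). Of 15345 genes 5037 were called with both siRNAs, of which 1809 were higher with both, 1704 were lower with both and 1524 moved in opposite directions. At a fold change of at least 2 with each siRNA, 290 genes were higher with both and 73 were lower with both.

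Among the other genes with the largest rise shared by both siRNAs were CEMIP, a hyaluronan-binding protein (log2 fold change 2.94 and 2.95), the synaptotagmin SYT12 (3.17 and 3.04), SOST, a secreted Wnt inhibitor (3.46 and 4.23), MAFA, a large Maf transcription factor (4.35 and 4.93), and GRHL3, a grainyhead transcription factor of epithelia (5.34 and 3.71), with siRNA1 given first. SLC1A7, S100P, SYT8, MGAT3, LINC02015 and KLRC3 completed these 12 genes, all from under 0.2 CPM in control libraries to 0.495 to 5.29 CPM with the siRNAs. Control libraries also held few counts of SOST (1 to 5), MAFA (0 to 2) and GRHL3 (0 to 2). The size of a rise from so few counts is uncertain. KLRC3 has close paralogs and overlaps another gene on the same strand, so its reads are uncertain. The shared drops after AXL included GJA1, the main connexin of gap junctions, from 25.2 ± 1.06 CPM to 7.65 ± 0.225 with siRNA1 and 4.51 ± 0.897 CPM with siRNA2. The metalloprotease ADAMTS6 fell with both (log2 fold change -2.40 and -1.56), as did LINC00707 (-2.65 and -1.81), and SNCAIP, a synuclein-binding protein (-1.79 and -1.53). RAPGEF5, an exchange factor of Rap GTPases (-1.74 and -1.61), the potassium channel KCNK12 (-1.52 and -2.002) and CT75 (-1.93 and -1.59) fell as well. LNCOC1, RGCC, NPM1P39 and TFR2 were below 1.3 CPM in control libraries, and each passed with both siRNAs but lost its call with siRNA1 when 1 library was left out. LNCOC1 had an adjusted p of 0.0797 without control library 1, and NPM1P39 0.0726 without siRNA1 library 3. RGCC had 0.0576 without control library 2 and 0.0711 without siRNA1 library 2, and with siRNA2 it had 0.0558 without siRNA2 library 2. TFR2 had 0.0778 without control library 3 and 0.0687 without siRNA1 library 1. The 3 prime UTRs of AXL, SNCAIP, KCNK12 and SOST hold the siRNA1 word, those of CEMIP and TFR2 the siRNA2 word, and that of ADAMTS6 both. CEMIP, KCNK12, LNCOC1, GRHL3 and SLC1A7 overlap a gene on the opposite strand, whose reads could not be told apart.

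Of the 48 tested genes of the G1/S and E2F list 40 were lower with both siRNAs and 0 were higher with both. E2F8, a repressor of the E2F family, fell from 33.7 ± 1.64 CPM to 15.8 ± 1.07 and 14.9 ± 1.56 CPM, and E2F2, an activator of that family, from 14.6 ± 0.917 to 10.4 ± 0.123 and 4.5 ± 1.08 CPM. CCNE2, a cyclin of S phase entry, fell from 18 ± 0.706 to 9.59 ± 1.14 and 8.15 ± 1.05 CPM, and POLA1, the catalytic subunit of DNA polymerase alpha, from 55.9 ± 3.23 to 35.1 ± 1.76 and 19.5 ± 0.5 CPM. In the ribosome biogenesis list 25 of 40 genes were lower with both, among them TCOF1 (log2 fold change -0.74 and -1.32) and DKC1 (-0.35 and -1.58). In the spliceosome list 19 of 39 were lower with both, among them PRPF4 (-0.78 and -0.80) and SF3A1 (-0.44 and -1.10). Of the MYC target list 16 of 28 were lower with both, such as SRM, the spermidine synthase (-0.36 and -1.13). CCNE2, POLA1 and TCOF1 overlap a gene on the opposite strand. PRPF4 and DKC1 hold the siRNA2 word and SF3A1 the siRNA1 word.

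Genes higher with both siRNAs included 12 of 23 TGF-beta targets, 15 of 34 lysosome and autophagy genes, 11 of 22 chaperones of the endoplasmic reticulum and 9 of 21 epithelial genes. In these lists 4, 8, 4 and 2 genes were called in opposite directions. With siRNA1 the chaperone list did not pass camera (median 0.15, adjusted p = 0.581). There 11 genes rose (12 adjusted over the list alone) and 6 fell. The epithelial list did not pass camera with siRNA2 (adjusted p = 0.0837). The TGF-beta targets PMEPA1 (log2 fold change 1.87 and 2.08), TGFBI (1.84 and 1.50), ID2 (2.61 and 1.26) and NEDD9 (4.53 and 1.95) rose with both. COL1A1, the main chain of type I collagen, rose from 8.25 ± 1.24 CPM to 45.1 ± 3.99 and 61.3 ± 2.22 CPM, and PDGFRB, a receptor of mesenchymal cells, from 1.23 ± 0.424 to 7.57 ± 0.494 and 6.84 ± 0.538 CPM. Both are also on the list of fibroblast markers. The epithelial genes ELF3 (2.31 and 2.20) and SPINT1 (2.11 and 1.61) rose as well. GABARAPL1 of autophagy (1.30 and 2.17), the lysosomal protease CTSD (1.15 and 0.75), and the chaperones HSPA5 (0.47 and 1.18) and DNAJB9 (0.76 and 1.91) rose with both. PMEPA1 holds both words, ELF3 the siRNA1 word and PDGFRB the siRNA2 word, and ELF3 overlaps an antisense gene.

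**Figure D3:**
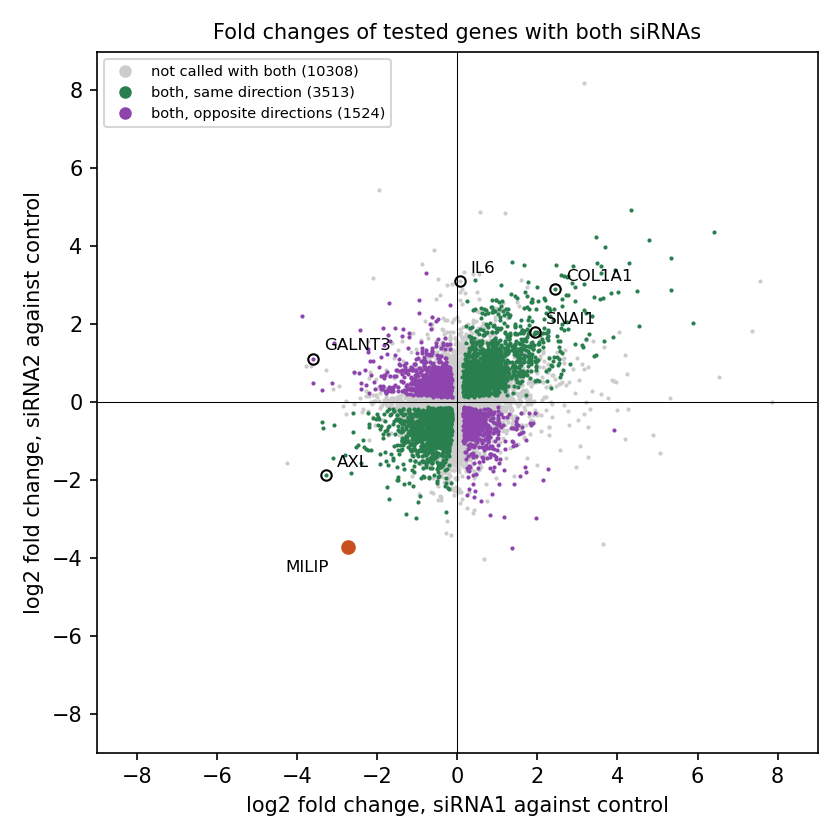
Log2 fold change against control with siRNA1 (horizontal) and with siRNA2 (vertical) for each of 15345 tested genes, coloured green where both siRNAs called the gene in 1 direction (3513 genes), purple where they called it in opposite directions (1524) and grey elsewhere. MILIP lies in the lower left, and IL6 and GALNT3 mark changes that the siRNAs did not share.

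Independent lists of the same sizes would share 1047 genes higher and 1123 lower with both siRNAs and 2170 in opposite directions, against 1809, 1704 and 1524 observed. In 20 simulations of unchanged groups against shared controls the highest count in 1 direction was 0, against 3513 observed. Those groups had at most 2 calls with siRNA1, so that count could not come near it. Across genes, which are not independent replicates, the fold changes with the siRNAs had a Pearson r of 0.333, against 0.521 in simulated unchanged groups, and a covariance of 0.154 against 0.0263 on the same genes, a difference of 0.128. The counts were not repeated with split controls, since 3 control libraries do not leave 2 for each siRNA, so part of the excess over independent lists may come from the shared controls. With siRNA1 as the reference in place of the control siRNA 4441 genes went in 1 direction in both other groups, and with siRNA2 as the reference 5663, so the count does not show by itself that the siRNA groups are the pair that moved together.

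With siRNA1 41 of 48 G1/S genes fell, and 38 of 55 respiratory chain genes, 14 of 23 TGF-beta targets and 14 of 21 epithelial genes rose. These 4 lists lost their call (adjusted p = 0.414, 0.896, 0.414 and 0.414 with an estimated correlation). GALNT3, which starts mucin-type O-glycosylation, fell from 42.1 ± 0.175 CPM to 3.48 ± 0.321 CPM (log2 fold change -3.60, adjusted p = 5.68e-19). TWF1, an actin-binding twinfilin, fell from 88.6 ± 9.55 to 8.6 ± 1.3 CPM, and TXNDC5, a protein disulfide isomerase, from 39.5 ± 3.95 to 3.83 ± 0.428 CPM. ALPP, placental alkaline phosphatase, rose from 0.213 ± 0.171 to 12.6 ± 3.07 CPM, and DUSP9, a MAP kinase phosphatase, from 0.0818 ± 0.031 to 3.55 ± 0.457 CPM (SD, n = 3 per group). In all 7738 genes were called with siRNA1, 3852 higher and 3886 lower, of which 858 and 654 changed at least 2-fold.

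Of the genes with 0 counts in every control library, those with the largest rise with siRNA1 were SLC6A19, a neutral amino acid transporter, at 1.66 ± 0.29 CPM (at least 8.89-fold higher, with 3 counts per control library as the floor), STYXL2 at 1.36 ± 0.0415 CPM (at least 7.27-fold) and TREM2 at 1.17 ± 0.0585 CPM (at least 6.25-fold). TNFSF18, a ligand of the tumour necrosis factor family, was at 0.0196 ± 0.0339 CPM in control libraries and 2.58 ± 0.306 CPM with siRNA1. NPR1, a natriuretic peptide receptor, fell from 0.373 ± 0.022 to 0.0187 ± 0.0324 CPM. BOLA2B fell from 3.36 ± 3.68 to 0.172 ± 0.0629 CPM, a control SD above the control mean, and lost its call with limma on FPKM. BOLA2B may share reads with a near-identical copy, as the pseudogene TWF1P1 (log2 fold change -3.61) may with TWF1, which was not tested. GALNT3, TXNDC5, TWF1 and ALPP hold the siRNA1 word, and BOLA2B and STYXL2 overlap a gene on the opposite strand. Among genes with an annotated 3 prime UTR, 62.7% of the 526 that fell at least 2-fold with siRNA1 held that word or its form. The share was 18.1% of the 8996 not called lower. The word was picked on these same fold changes and UTR length was not matched, so the difference is not separate evidence.

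Of 34 gene lists, 11 were called with siRNA1 by camera with a preset correlation of 0.01, 5 lower and 6 higher, and with an estimated correlation 0 of these 11 were called. Counts are over all genes tested, and the number adjusted over the list alone is the same unless given. In the G1/S list 41 of 48 genes fell and 0 rose (median log2 fold change -0.51, adjusted p = 4.8e-11, and adjusted p = 0.414 with an estimated correlation). In ribosome biogenesis 25 of 40 fell and 3 rose (26 lower adjusted over the list alone; median -0.22, adjusted p = 0.00171, and adjusted p = 0.529 with an estimated correlation), such as NOP14 (-1.20), which holds the siRNA1 word and overlaps an antisense gene. Of MYC targets 18 of 28 fell and 3 rose (-0.19, adjusted p = 0.00663, and adjusted p = 0.52 with an estimated correlation), such as CAD of pyrimidine synthesis (-1.13), which holds the siRNA1 word. Of spliceosome genes 21 of 39 fell and 3 rose (-0.17, adjusted p = 0.0373, and adjusted p = 0.529 with an estimated correlation), a call lost without control library 3 (adjusted p = 0.0694) and with a minimum mean FPKM of 1 or 5. In the cholesterol list 18 of 32 fell (20 adjusted over the list alone) and 6 rose (-0.17, adjusted p = 0.00527, and adjusted p = 0.414 with an estimated correlation), and the call was lost with limma on FPKM and without genes that hold either word. Its largest drop was the fatty acid desaturase FADS1, from 315 ± 22.6 to 36 ± 0.992 CPM, which holds the siRNA1 word and overlaps FADS2 on the opposite strand.

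Among lists higher with siRNA1, 38 of 55 nuclear-encoded respiratory chain genes rose and 1 fell (median 0.25, adjusted p = 0.00439, and adjusted p = 0.896 with an estimated correlation). NDUFA4 rose from 68.3 ± 4.58 to 106 ± 2.67 CPM, and the gene that fell was COX8A, from 411 ± 25.4 to 126 ± 10.6 CPM, which holds the siRNA1 word. Beside this list, the mitochondrial ribosomal RNA share was 0.622% of counts in control libraries and 1.1% with siRNA1. Of TGF-beta targets 14 of 23 rose and 3 fell (15 higher adjusted over the list alone; median 0.70, adjusted p = 1.14e-06, and adjusted p = 0.414 with an estimated correlation). Of epithelial genes 14 of 21 rose and 3 fell (15 higher adjusted over the list alone; median 0.72, adjusted p = 0.000324, and adjusted p = 0.414 with an estimated correlation), such as the cadherin CDH3, from 0.441 ± 0.192 to 6.95 ± 0.631 CPM, which overlaps an antisense gene. Of lysosome and autophagy genes 17 of 34 rose and 8 fell (0.18, adjusted p = 0.0311, and adjusted p = 0.718 with an estimated correlation). Of immediate early genes 15 of 30 rose and 6 fell (7 lower adjusted over the list alone; 0.17, adjusted p = 0.0366, and adjusted p = 0.702 with an estimated correlation), such as DUSP1 (1.76). Both calls were lost with limma on FPKM, that of lysosome genes also with a minimum mean FPKM of 5. That of immediate early genes was lost without genes that hold either word, without control library 1 (adjusted p = 0.0666) and without siRNA1 library 1 (0.0608). Of 7 fibroblast markers 3 rose and 1 fell (0.68, adjusted p = 0.00704, and adjusted p = 0.414 with an estimated correlation), with COL1A1 and PDGFRB among the 3, and the median is 0.68 also without COL1A2 and COL3A1, which were at or under the 3-count limit in both groups. Mesenchymal genes had a median of -0.019, or 0.011 without COL3A1 (11 of 30 higher and 13 lower, adjusted p = 0.183). Of the 5 endothelial markers 4 fell, among them ESAM (-0.89) and KDR (-0.92), and the list did not pass (median -0.62, adjusted p = 0.0752). Of 5 leukocyte markers 1 rose (0 adjusted over the list alone) and 1 fell (median 0.030, mean -0.080, adjusted p = 0.852).

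With siRNA2 the lists of ribosome biogenesis and G1/S genes fell and those of inflammatory, mesenchymal and cholesterol synthesis genes rose. These 5 lists kept their call (adjusted p = 0.00904 for cholesterol synthesis and 0.0449 for each of the others with an estimated correlation). IL6, a cytokine driven by NF-kappa-B, rose from 31.2 ± 1.24 CPM to 269 ± 32.4 CPM (log2 fold change 3.10, adjusted p = 2.51e-19). HMGCS1, which makes the precursor of mevalonate, rose from 65.2 ± 4.98 to 396 ± 11.3 CPM (2.60, adjusted p = 2.51e-19), and CDKN1A, a cell cycle inhibitor and p53 target, from 185 ± 8.06 to 429 ± 27.6 CPM (1.22, adjusted p = 1.5e-14). The splicing factor SF3A3 fell from 211 ± 4.13 to 54.8 ± 2.09 CPM, and PCBD1, an enzyme of tetrahydrobiopterin recycling, from 24 ± 2.01 to 2.27 ± 0.381 CPM (SD, n = 3 per group). In all 8606 genes were called with siRNA2, 4172 higher and 4434 lower, of which 930 and 740 changed at least 2-fold.

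The chemokine CCL20 rose from 0.336 ± 0.195 to 10 ± 1.6 CPM with siRNA2 and CXCL5 from 0.385 ± 0.419 to 5.66 ± 1.04 CPM. TNFSF15, a tumour necrosis factor family ligand, rose from 1.15 ± 0.277 to 14.1 ± 0.278 CPM. COL1A2 had 0 counts in every control library and reached 2.07 ± 0.184 CPM (at least 11.1-fold higher, with the same floor), COL3A1 rose from 0.0196 ± 0.0339 to 1.21 ± 0.124 CPM, and SYNGR3 from 0.0622 ± 0.00366 to 1.99 ± 0.274 CPM. CHRDL1, a BMP antagonist, fell from 13.4 ± 0.26 to 1.69 ± 0.132 CPM and HIF1A-AS3 from 7.37 ± 0.837 to 0.884 ± 0.395 CPM. USP2-AS1, SLC29A4 and SNX25P1 fell from under 0.7 CPM to under 0.06 CPM. CXCL5, SYNGR3, USP2-AS1, SLC29A4 and HIF1A-AS3 overlap a gene on the opposite strand and SNX25P1 lies in LINC00467 on the same strand. PCBD1 holds the siRNA2 word, and TNFSF15, COL3A1, SLC29A4 and CHRDL1 the siRNA1 word. Among genes with an annotated 3 prime UTR, 34.1% of the 572 that fell at least 2-fold with siRNA2 held the siRNA2 word or its form. The share was 8.23% of the 8622 not called lower. This word too was picked on the same fold changes, without matching UTR length, so the difference is not separate evidence.

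Of 34 lists, 22 were called with siRNA2, 10 lower and 12 higher, and with an estimated correlation 9 of them were called. The lists that fell and kept the call were G1/S genes, 46 of 48 lower (median -0.64, adjusted p = 1.8e-18, and adjusted p = 0.0449 with an estimated correlation), and ribosome biogenesis, 37 of 40 lower (-0.86, adjusted p = 6.57e-24 and 0.0449). So did MYC targets, 24 of 28 lower (-0.62, adjusted p = 1.78e-11 and 0.0449), and spliceosome genes, 30 of 39 lower (31 adjusted over the list alone; -0.34, adjusted p = 1.36e-07 and 0.0449). DKC1, a catalytic protein of RNA modification, fell from 166 ± 3.91 to 55.7 ± 4.57 CPM. MYC itself fell by 0.55 on the log2 scale (adjusted p = 4.23e-08) and holds the siRNA2 word. Cytosolic ribosomal protein genes fell in 77 of 80 (78 adjusted over the list alone; median -0.42, adjusted p = 6.3e-14, and adjusted p = 0.331 with an estimated correlation), such as RPL18, from 459 ± 47.1 to 183 ± 8.78 CPM, which holds the siRNA2 word. RACK1 fell from 1938 ± 115 to 998 ± 8.04 CPM. Mitotic genes fell in 40 of 46 (41 adjusted over the list alone; -0.49, adjusted p = 3.65e-10, and adjusted p = 0.19 with an estimated correlation), such as GTSE1 (-1.39) and the checkpoint gene MAD2L1 (-1.28), which holds the siRNA1 word. Translation factors fell in 36 of 44 (-0.36, adjusted p = 2.13e-08, and adjusted p = 0.0762 with an estimated correlation), led by EIF3M (-1.57). The tRNA synthetases fell in 15 of 22 and rose in 2 (18 lower adjusted over the list alone; -0.28, adjusted p = 3.3e-05, and adjusted p = 0.0501 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 29 of 39 (31 adjusted over the list alone; -0.42, adjusted p = 6.48e-06, and adjusted p = 0.322 with an estimated correlation), such as MRPS26 (-1.20), which holds the siRNA2 word. Respiratory chain genes fell in 24 of 55 and rose in 3 (-0.14, adjusted p = 0.0263, and adjusted p = 0.673 with an estimated correlation), led by COX6B1, from 121 ± 8.49 to 43.9 ± 1.13 CPM, and that list lost its call without control library 3 (adjusted p = 0.128) and with a minimum mean FPKM of 1 or 5.

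The lists that rose with siRNA2 and kept the call were cholesterol synthesis, 26 of 32 higher (median 0.65, adjusted p = 1.08e-21, and adjusted p = 0.00904 with an estimated correlation), and NF-kappa-B and inflammatory genes, 26 of 31 higher (27 adjusted over the list alone; 1.02, adjusted p = 1.18e-23 and 0.0449). The others were mesenchymal genes, 23 of 30 higher and 4 lower (0.52, adjusted p = 6.17e-10 and 0.0449), histones, 9 of 17 higher (10 adjusted over the list alone; 0.63, adjusted p = 4.63e-05 and 0.0449), and p53 targets, 16 of 27 higher and 7 lower (0.40, adjusted p = 0.000416 and 0.0449). INSIG1, a sterol-regulated protein of the endoplasmic reticulum, rose from 56.2 ± 2.33 to 318 ± 14.4 CPM and MSMO1, a sterol oxidase, from 30.2 ± 2.43 to 155 ± 6.77 CPM. Linker histone H1-2 rose from 8.38 ± 0.719 to 41.8 ± 2.62 CPM. The p53 targets BBC3 (1.56) and SESN1 (0.94) rose, while MDM2, an antagonist of p53 and one of its targets, fell by 0.32 on the log2 scale. TGF-beta targets rose in 20 of 23 (1.01, adjusted p = 9.27e-16, and adjusted p = 0.0501 with an estimated correlation). Lysosome and autophagy genes rose in 30 of 34 (0.53, adjusted p = 5.53e-11, and adjusted p = 0.0543 with an estimated correlation), such as ULK1, a kinase that starts autophagy (1.80). Chaperones of the endoplasmic reticulum rose in 20 of 22 (21 adjusted over the list alone; 0.50, adjusted p = 2.48e-09, and adjusted p = 0.0501 with an estimated correlation), such as HERPUD1 (1.40). Interferon genes rose in 24 of 45 (26 adjusted over the list alone) and fell in 7 (8 adjusted over the list alone; 0.34, adjusted p = 0.0084, and adjusted p = 0.1 with an estimated correlation), with IFI6 higher (1.42) and OAS3 lower (-0.98), which holds both words. NRF2 targets rose in 12 of 22 and fell in 3 (0.19, adjusted p = 0.0133, and adjusted p = 0.434 with an estimated correlation), such as AKR1C3 (1.18), which has close paralogs. Pro-apoptotic genes rose in 14 of 22 and fell in 5 (0.32, adjusted p = 0.0263, and adjusted p = 0.0836 with an estimated correlation), such as BMF (2.29) and BIK (2.65). Calls of the interferon, NRF2 and pro-apoptotic lists were lost when only genes with a mean FPKM of at least 5 were tested, and that of NRF2 targets also without genes that hold either word.

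Some markers of other cell types also moved with siRNA2, beside the mesenchymal genes. Of the fibroblast, leukocyte, endothelial and epithelial lists only the first passed camera at the preset correlation. Of 12 fibroblast, 16 leukocyte and 10 endothelial markers 7, 5 and 5 had enough counts to be tested. Of 7 fibroblast markers 5 rose and 1 fell (median 2.48, adjusted p = 3.31e-05, and adjusted p = 0.0501 with an estimated correlation), with COL1A2, COL1A1, PDGFRB and COL3A1 among the 5, and the median is 2.48 also with COL1A2 at its bound. Of 5 leukocyte markers 4 rose and 1 fell (median 1.253, adjusted p = 0.0828), with CD14 at 2.11 ± 0.565 CPM in control libraries and 8.49 ± 0.31 CPM with siRNA2. Of 5 endothelial markers 2 rose, KDR (1.53) and PECAM1 (0.62), and 1 fell (median 0.087, adjusted p = 0.409). PECAM1 holds the siRNA2 word. Of 21 epithelial genes 11 rose (12 adjusted over the list alone) and 3 fell (median 0.33, adjusted p = 0.0837). The mitochondrial ribosomal RNA share was 0.622% of counts in control libraries and 0.893% with siRNA2, while 6 of 13 mitochondrially encoded genes fell (5 adjusted over the list alone; median -0.14, adjusted p = 0.235).

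**Figure D4:**
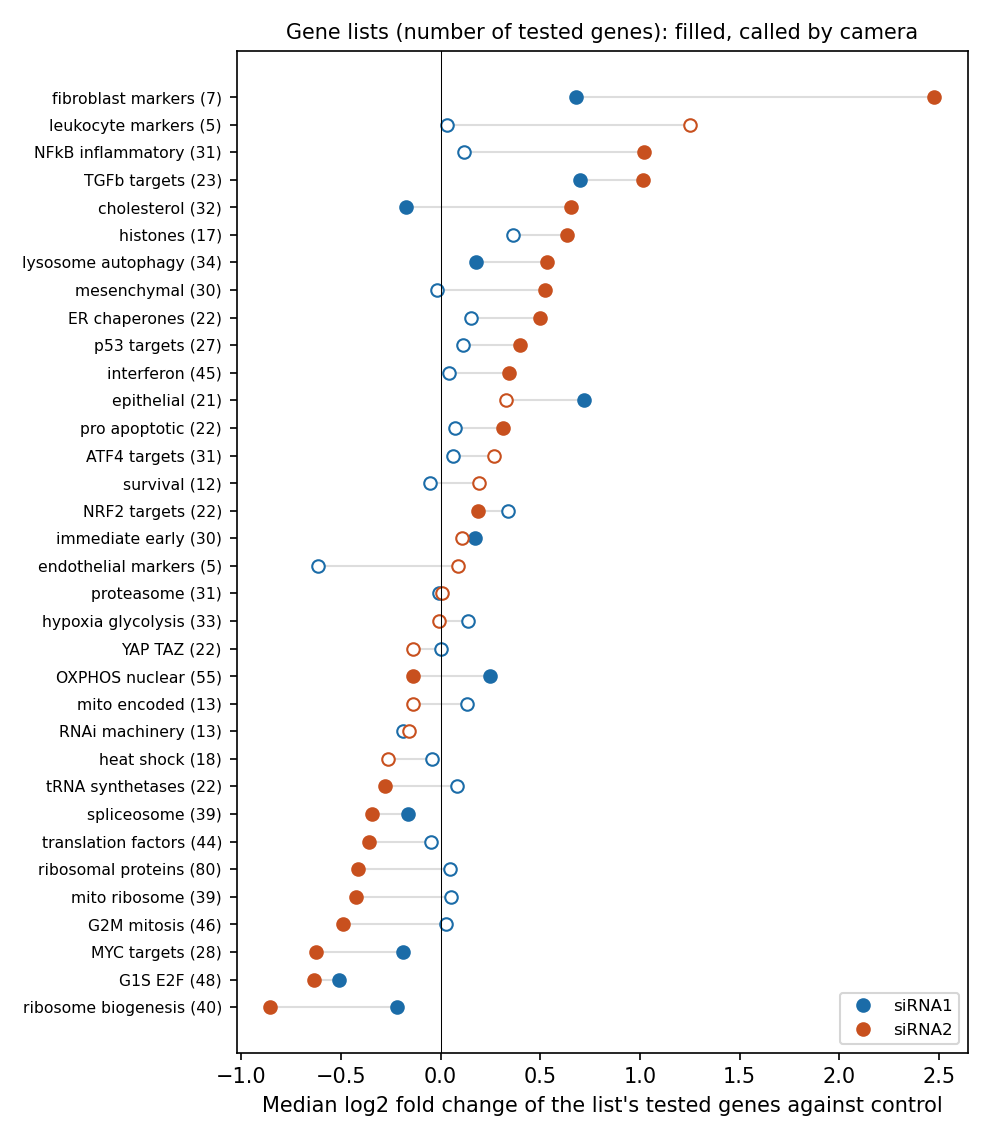
Median log2 fold change against control of the tested genes of each of 34 gene lists with siRNA1 (blue) and siRNA2 (orange), with the number of tested genes in brackets and filled points where camera with a preset correlation called the list. G1/S genes lie at -0.51 and -0.64, cholesterol genes at -0.17 and 0.65, and respiratory chain genes at 0.25 and -0.14.

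Other lists passed with neither siRNA, with medians given for siRNA1 and then siRNA2. ATF4 targets had 0.062 and 0.27 (12 and 15 of 31 higher, 16 with siRNA2 adjusted over the list alone, and 10 and 11 lower), although GDF15 rose with both (2.08 and 1.72). Survival genes had -0.055 and 0.19 (3 and 6 of 12 higher, 5 and 3 lower), and hypoxia and glycolysis genes 0.14 and -0.010 (14 and 16 of 33 higher, 15 with siRNA1 adjusted over the list alone, and 10 and 12 lower, 13 with siRNA2 adjusted over the list alone). Heat shock genes had -0.045 and -0.26 (7 and 6 of 18 higher, 8 and 10 lower, 11 with siRNA2 adjusted over the list alone) and YAP and TAZ targets 0.0040 and -0.14 (9 and 6 of 22 higher, 7 with siRNA2 adjusted over the list alone, and 5 and 10 lower). Proteasome genes had -0.0090 and 0.0080 (4 and 7 of 31 higher, 6 and 4 lower), and genes of RNA interference -0.19 and -0.16 (4 and 5 of 13 higher, 6 and 6 lower, 7 with siRNA1 adjusted over the list alone). Mitochondrially encoded genes had 0.13 with siRNA1 (6 of 13 higher, 0 lower). The median, the mean and the test differed in sign for interferon genes with siRNA1 (median 0.043, mean -0.010, adjusted p = 0.946), inflammatory genes with siRNA1 (0.12, -0.088, 0.62) and heat shock genes with siRNA1 (-0.045, 0.0080, 0.946). The same held for hypoxia genes with siRNA2 (-0.010, 0.16, 0.372), genes of RNA interference with siRNA2 (-0.16, 0.021, 0.852) and between the siRNAs (-0.055, 0.11, 0.759), and proteasome genes with siRNA2 (0.0080, -0.032, 0.708).

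The siRNAs differed from each other more than either did from the control siRNA, with 9271 genes called between them (4360 higher and 4911 lower with siRNA2), of which 1159 and 1126 differed at least 2-fold. GALNT3 was at 3.48 ± 0.321 CPM with siRNA1 and 91.1 ± 4.46 CPM with siRNA2 (log2 fold change 4.71, adjusted p = 7.96e-22), while it was at 42.1 CPM in control libraries. The guanine nucleotide exchange factor RASGRP2 was at 5.09 ± 1.29 CPM with siRNA1 and 0.0508 ± 0.0879 CPM with siRNA2, and NPR1 at 0.0187 ± 0.0324 and 1.78 ± 0.732 CPM. SERPINB4 (0.0422 ± 0.0731 and 1.76 ± 0.67 CPM) and BCL2A1, a BCL2 family survival gene (0.0358 ± 0.0311 and 1.08 ± 0.209 CPM), were higher with siRNA2. CALML5, a calmodulin-like protein of skin (3.24 ± 0.619 and 0.0533 ± 0.051 CPM), and PADI2, a protein arginine deiminase (1.1 ± 0.25 CPM and 0 counts in every library), were higher with siRNA1 (SD, n = 3 per group). PADI2 holds the siRNA2 word. All 1524 genes that the siRNAs called in opposite directions were also called in the test of the difference, 666 of them higher with siRNA1 and lower with siRNA2 and 858 the other way.

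Genes of the fixed set moved with both siRNAs, with 1 or with neither. TRIM28, a transcriptional corepressor, was at -0.062 with siRNA1 (adjusted p = 0.448) and fell by 0.56 with siRNA2. The translation factor EEF1A1 rose by 0.32 with siRNA1, a call lost after quantile normalization of FPKM, and was at 0.0080 with siRNA2 (adjusted p = 0.898). CDKN1A was at -0.12 with siRNA1 (adjusted p = 0.117). MYC was at -0.145 with siRNA1, at an adjusted p of 0.05 and outside the call, and DESeq2 or median-of-ratios scaling called it. YBX1, an RNA-binding protein, fell with both (-0.96 and -0.69) and holds the siRNA1 word, as do MDM2 (-0.55 and -0.32) and ACTB (-0.39 and -0.24). GAPDH fell by 0.33 and 0.30, but its value with siRNA2 was 0 after quantile normalization of FPKM. VIM was at -0.049 with siRNA1 (adjusted p = 0.435) and fell by 0.23 with siRNA2, a call lost after quantile normalization, and MELTF was at 0.018 and 0.015 (adjusted p = 0.849 and 0.866).

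Between the siRNAs 21 of 34 lists were called, 10 higher and 11 lower with siRNA2, and cholesterol synthesis alone kept the call with an estimated correlation (27 of 32 higher and 2 lower, 3 adjusted over the list alone; median 1.12, adjusted p = 1.11e-26, and adjusted p = 0.00306 with an estimated correlation). In that list 16 genes were called in opposite directions against control. Higher with siRNA2 were also inflammatory genes (23 of 31, with 3 lower; median 0.78, adjusted p = 2.88e-19, and adjusted p = 0.0913 with an estimated correlation) and mesenchymal genes (21 of 30, with 4 lower; 0.49, adjusted p = 2.77e-11, and adjusted p = 0.0755 with an estimated correlation). So were chaperones of the endoplasmic reticulum (19 of 22; 0.50, adjusted p = 8.4e-06, and adjusted p = 0.176 with an estimated correlation) and lysosome and autophagy genes (23 of 34, with 8 lower; 0.47, adjusted p = 0.00033, and adjusted p = 0.274 with an estimated correlation). Histones (10 of 17, with 2 lower; 0.86, adjusted p = 0.00762, and adjusted p = 0.176 with an estimated correlation) and TGF-beta targets (12 of 23, with 9 lower; 0.60, adjusted p = 0.00848, and adjusted p = 0.474 with an estimated correlation) were higher too. The last lists higher with siRNA2 were p53 targets (12 of 27, with 9 lower; 0.12, adjusted p = 0.0247, and adjusted p = 0.176 with an estimated correlation), endothelial markers (3 of 5; 0.98, adjusted p = 0.0247, and adjusted p = 0.176 with an estimated correlation) and interferon genes (26 of 45, 27 adjusted over the list alone, with 8 lower; 0.47, adjusted p = 0.0275, and adjusted p = 0.238 with an estimated correlation). The calls of TGF-beta targets, p53 targets and endothelial markers were lost with limma on FPKM, and that of endothelial markers without siRNA1 library 2 (adjusted p = 0.054). With a minimum mean FPKM of 1 the calls of p53 targets, interferon genes and endothelial markers were lost.

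Lower with siRNA2 than with siRNA1 were ribosomal protein genes (76 of 80, 77 adjusted over the list alone; median -0.44, adjusted p = 1.84e-12, and adjusted p = 0.408 with an estimated correlation) and mitotic genes (39 of 46; -0.53, adjusted p = 7.13e-09, and adjusted p = 0.274 with an estimated correlation). The same held for ribosome biogenesis (35 of 40; -0.59, adjusted p = 4.56e-09, and adjusted p = 0.176 with an estimated correlation), for tRNA synthetases (17 of 22, with 3 higher; -0.48, adjusted p = 8.12e-06, and adjusted p = 0.0913 with an estimated correlation) and for respiratory chain genes (42 of 55, 45 adjusted over the list alone; -0.38, adjusted p = 8.4e-06, and adjusted p = 0.474 with an estimated correlation), of which 17 were called in opposite directions against control. All 13 mitochondrially encoded genes were lower (median -0.30, adjusted p = 0.0342, and adjusted p = 0.518 with an estimated correlation). Mitochondrial ribosomal proteins (33 of 39, 34 adjusted over the list alone; -0.47, adjusted p = 1.05e-05, and adjusted p = 0.361 with an estimated correlation) and translation factors (35 of 44, with 4 higher; -0.33, adjusted p = 0.000269, and adjusted p = 0.253 with an estimated correlation) were lower as well. Lower too were MYC targets (20 of 28, 23 adjusted over the list alone, with 3 higher; -0.45, adjusted p = 0.00101, and adjusted p = 0.253 with an estimated correlation), spliceosome genes (23 of 39, with 4 higher; -0.25, adjusted p = 0.0116, and adjusted p = 0.253 with an estimated correlation) and G1/S genes (22 of 48, with 6 higher; -0.13, adjusted p = 0.0365, and adjusted p = 0.518 with an estimated correlation). The G1/S call was lost without siRNA2 library 1 (adjusted p = 0.0864) and without genes that hold either word. The call of mitochondrially encoded genes was lost without siRNA1 library 1 (0.063), siRNA1 library 2 (0.0539) or siRNA2 library 3 (0.0571) and after quantile normalization of FPKM, and both were lost with a minimum mean FPKM of 1 or 5.

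**Figure D5:**
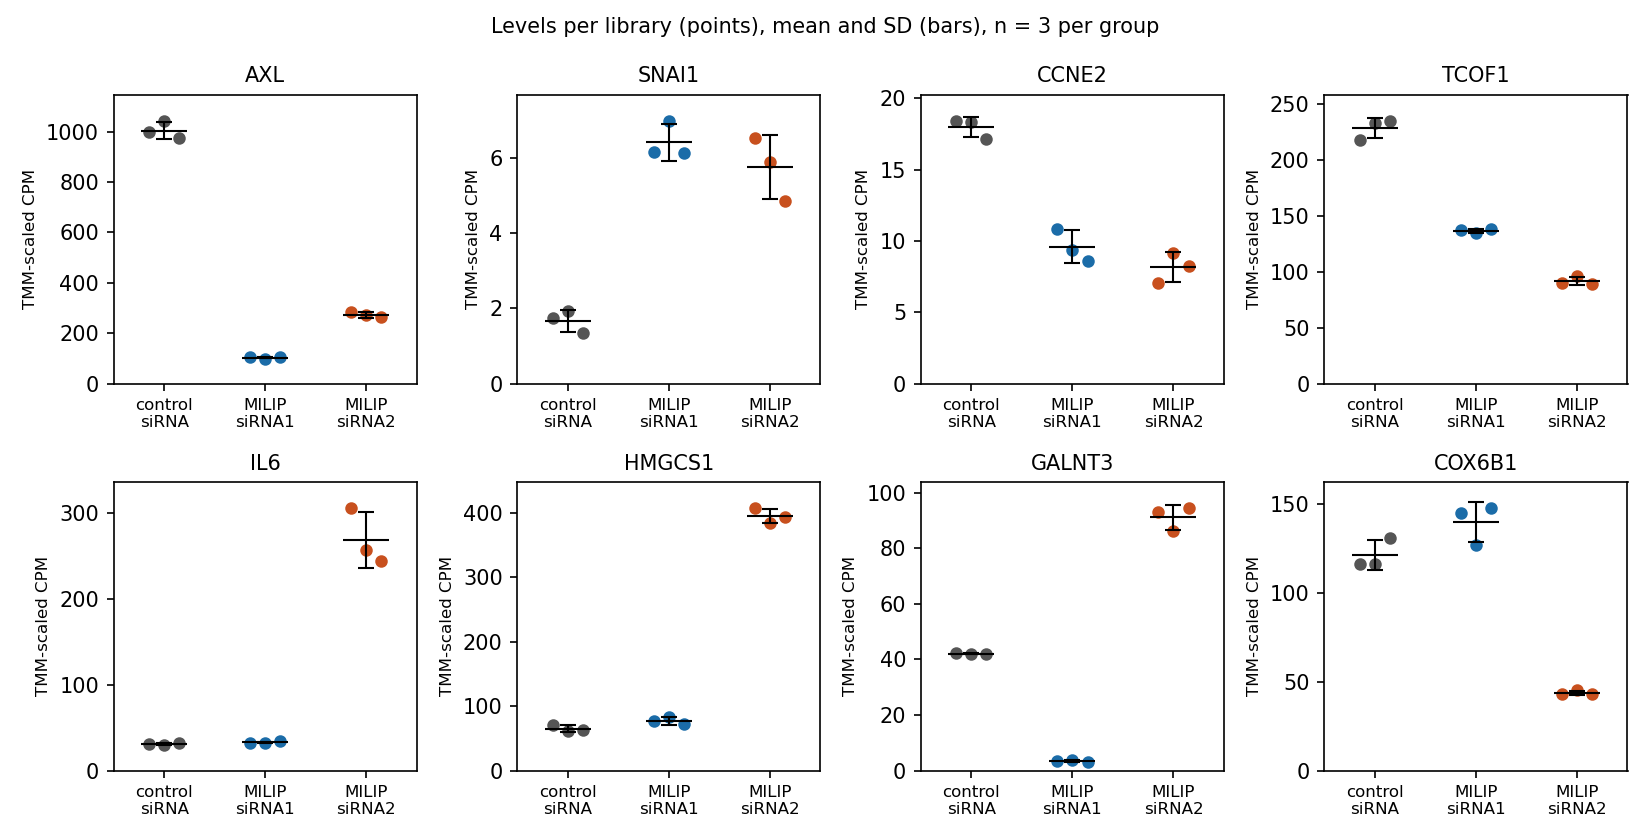
CPM of 8 genes in each of the 9 libraries (points), with the group mean and SD as bars (n = 3 per group). AXL, CCNE2 and TCOF1 were lower and SNAI1 higher with both siRNAs, IL6 and HMGCS1 were higher with siRNA2, GALNT3 was lower with siRNA1 and higher with siRNA2, and COX6B1 was lower with siRNA2 and overlapped control with siRNA1.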

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

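The tests of words found against control, of words as the whole cause, of a deeper loss of MILIP, of separate control libraries and of the reference group were chosen only after the result was seen. The other tests had their predictions written before their results were known. At least those on gene length and GC and on genes near MILIP took up patterns already seen. These results stood out because the siRNAs, both against MILIP, differed when tested against each other: 1524 genes called in opposite directions, the cholesterol list (median difference 1.121) and the respiratory chain list (median difference -0.378).

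Genes differed between the siRNAs, with 9271 called. A deeper loss of MILIP with siRNA2 predicts changes in 1 direction, provided that each gene responds to MILIP in 1 direction. Of the genes called with both siRNAs 30.3% moved in opposite directions, which argues against it as the whole cause. A part in the differences beside other causes is not excluded. Silencing of other transcripts through the siRNA seeds may account for part: the word ranked lowest by t from siRNA1 to siRNA2, ACCCTAA, had t = -12.95 (shift -0.319) against a largest shuffled value of 5.18. It is absent from MILIP and is the form 1 base along of the word ranked second, GACCCTA (t = -12.6, shift -0.364), which MILIP holds. By this rank the criterion written beforehand was met by the first word only in the other direction (AATTCCA, t = 14.97). Each word's shift seen under the other siRNA was at most 0.0998 of its own. Holding these words or their forms is not the whole cause, since 64% of genes with neither were called between the siRNAs (5611 of 8763). Of genes with a word 69.8% were called (2632 of 3770). Genes with neither can hold related words such as ATTCCAG (t = -10.51 with siRNA1) and CCCTAAT (t = -10.32 with siRNA2), which this leaves open. Effects that follow from the first targets, sites outside 3 prime UTRs and a biological difference remain open as well.

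Genes moved together with both siRNAs, 3513 in 1 direction. For the control libraries shared by both comparisons, the highest simulated count of 0 decides nothing, since unchanged groups had at most 2 calls with siRNA1. With another control library for each siRNA the covariance of the folds was 0.0923 to 0.122 over 6 choices, against 0.134 with all shared (differences of mean log2 CPM in both, where edgeR's fitted fold changes gave 0.158 on the same 15345 genes, and 0.154 on the 15341 with counts in the control libraries), which argues against chance in the shared libraries as the whole cause, but part of the count may come from it. Against sites of both siRNAs' words as the whole cause, 1.59 times as many genes with neither word were lower with both as independent lists give (923 against 582). Those genes can hold other related words, so sites of such words stay open. A state of the control cultures of their own is not excluded. Taking siRNA1 as the reference gave 4441 genes and siRNA2 5663. Groups that all lie apart can give such counts with any reference, so these counts cannot decide it. Of 100 splits of the 9 libraries 3 gave as many genes, the real one included, with 5663 as the highest other, and both other splits had all 3 siRNA2 libraries as the reference, which points to the structure of the groups. A response to loss of MILIP remains open beside such a state and a response to active siRNAs as a class, which was not tested.

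Ribosomal protein genes, which are short (median exonic length 2918.5 against 4763 bases), were lower with siRNA2 by a median of -0.415. The median was -0.392 after the trend with exonic gene size and GC content of the longest transcript was removed (quartiles -0.543 and -0.3). That trend held 1.41% of the variance. This argues against a bias by these 2 measures as the cause. Exonic gene size is not the length of the expressed transcript, so a bias by transcript length is not decided. Other causes remain open, a biological one included, and the list lost its call with an estimated correlation (adjusted p = 0.331).

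For each comparison the 6 libraries make 10 splits, too few for a share under 0.05: 1 of 10 splits, the real one, gave as many calls with siRNA1 (7738, highest other 0), 1 of 10 with siRNA2 (8606, highest other 0) and 1 of 10 between the siRNAs (9271, highest other 0).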

How the results depend on the processing

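Leaving out genes that hold a word of either siRNA was the only alternative chosen after the data were seen. With a minimum mean FPKM of 5, which tests 6820 genes, calls numbered 4215 with siRNA1, 4905 with siRNA2, 5057 between the siRNAs and 2104 in 1 direction with both, and fewer genes tested accounts for a loss of calls by construction. With an absolute log2 fold change of at least 1 they numbered 1512, 1670, 2285 and 363, as a stricter threshold must give fewer. Camera with the preset correlation called 11 lists with siRNA1, 22 with siRNA2 and 21 between the siRNAs. With an estimated correlation it called 0, 9 and 1 in the same order, while fry called 20, 32 and 31. The alternatives thus moved these counts in both directions, and for both the cause was not tested. GAPDH with siRNA2 went from -0.30 to 0 (adjusted p = 1) with limma on quantile normalized FPKM, and the cause was not tested.

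For counts of calls, lists called and the MILIP level, 191 values under the other alternatives stayed on the same side or within 1.5 times. With a library left out, calls ranged from 6857 to 7668 with siRNA1, 7838 to 8925 with siRNA2, 8636 to 9634 between the siRNAs and 3078 to 3509 in 1 direction. Lists called ranged from 10 to 11, 21 to 22 and 19 to 22, and the MILIP log2 fold change from -3.221 to -2.409 with siRNA1 and -4.217 to -3.466 with siRNA2. DESeq2 made 7312, 8207 and 8849 calls, and without genes that hold either word there were 5378, 6232 and 6588. Among lists 2183 results were the same, 52 gained and 105 lost a call, and among named genes 7711 were the same, 55 gained, 149 lost and 1 reversed. With the replicate number as a replicate block there were 7750, 8604 and 9294 calls. The libraries share only a number: the deviations of same-numbered libraries correlated at -0.32 to 0.309 (3 of 9 pairs above 0.1), and 6 of 9 libraries correlated best with their own number. Differently numbered libraries reached 0.504 (control library 1 and siRNA1 library 2) and -0.402 (control library 3 and siRNA1 library 2). A block by number does not adjust for such links. At this depth, spread and number of libraries 78% of simulated 1.5-fold changes, placed in the more abundant genes, were recovered.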

Other observations

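The Gene Ontology tests were chosen only after the result was seen, as were those without MAFG or NOTUM. The test of genes near MILIP had its prediction written before its result was known, but took up the rise of MAFG, already seen. Genes of DNA strand elongation were lower with both siRNAs, 21 of 28 against 3.61 expected (adjusted p = 5.92e-11). They included GINS2 (log2 fold change -0.91 with siRNA1 and -0.87 with siRNA2), MCM3 (-0.78 and -0.76), MCM6 (-0.75 and -0.89) and CDC45 (-0.73 and -0.75), all parts of the replicative helicase. Splicing genes were lower in 56 of 126 against 16.3 expected (adjusted p = 2.36e-15), and DNA repair genes in 52 of 173 against 22.3 (adjusted p = 3.53e-07), such as RFWD3 (-1.07 and -1.53), a ubiquitin ligase of the replication fork, and CDK2 (-0.85 and -1.12). The term for regulation of glucose transport (18 of 31, 4 expected, adjusted p = 5.79e-07) held nucleoporins, with NUP42 (-0.62 and -0.64), NUP188 (-0.59 and -0.62), NUP155 (-0.43 and -0.76) and NUP43 (-0.66 and -0.43) its most lowered members. The terms were tested on 10615 annotated genes, and 42 of 1334 terms passed among genes lower with both. The hypergeometric test takes genes as independent, so its p-values, here and for the terms below, may be too small where genes of a term move together. The most lowered splicing members include YBX1P10, a pseudogene that may share reads with YBX1, which was not tested.

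Extracellular matrix genes were higher with both siRNAs, 23 of 77 against 9.91 expected (adjusted p = 0.0435), such as COL15A1, a basement membrane collagen (3.30 and 1.75). Genes of cell adhesion were higher in 14 of 35 against 4.5 expected (adjusted p = 0.0435), such as the Notch ligand JAG2 (1.79 and 1.12). Genes higher with siRNA1 and lower with siRNA2 were enriched for the respiratory electron transport chain (13 of 62 against 3.02, adjusted p = 0.00919), and genes lower with siRNA1 and higher with siRNA2 for N-linked glycosylation (17 of 88 against 5.87, adjusted p = 0.0393) and post-translational protein modification (26 of 170 against 11.3, adjusted p = 0.0393).

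MAFG, whose gene span ends 94 bases from the 5 prime end of MILIP, rose with both siRNAs, and loss of MILIP may raise genes near its locus. The 45 genes within 500 kb had a mean log2 fold change of 0.191 against 0.024 for all genes (one-sided permutation p = 0.0273), and 0.188 without MAFG (permutation p = 0.0302). Without NOTUM, a Wnt inhibitor chosen after its values were seen (2.67 and 3.24), the mean was 0.129 (permutation p = 0.109), so the result rests on 1 gene and leaves the question open. Of these genes 7 were higher and 3 lower with both.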
